A study of Mus musculus with 378 samples.

How the data were processed

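RNA was measured by poly(A)-selected sequencing in pancreatic islets of Diversity Outbred mice, an outbred stock in which every animal has its own mix of founder genomes. There were 378 libraries, 188 from females and 190 from males, each from a different mouse. Per the labels, the diet of all mice was high in fat and sugar (45% fat), and ERCC control RNA was added to each sample before library construction. Sex was read from the titles, which also number the mice. The labels name no batch. Because the numbers run in stretches of about 50 of a single sex, 4 number bands of 100 starting at 21 were set up before the data were examined, so that each band held both sexes. What a band stands for is not stated. Within a band, sex follows the stretch of numbers apart from mouse 191, a female numbered among males. In every band the stretch of females comes before that of males. A sex difference that returns in all 4 bands is therefore not that of a single stretch. An effect of the order within a band would return as well, so sex and this order are not separated.

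The deposited count table holds estimated counts per gene that the authors did not scale between libraries. Of its values 67.7% are whole numbers with a tolerance of 0, and the rest are fractional, as when reads are divided among genes that share sequence. The aligner and the counter are not given in the sources used here. GRCm38 and DESeq2 are named in the submitters' processing notes, without versions. The table lists 22180 genes, each above 0 in at least 190 libraries, and no ERCC row (0). The second deposited table holds the authors' variance-stabilised values on a log2-like scale, with library size removed. In these deposited log2 values, unlike in the counts, the number bands were more alike than random differences between mice would leave them. Band differences had therefore evidently been removed from them. How the authors made them beyond this is not given in the sources used here. The deposited gene table, whose other columns give gene starts and ends in megabases, provided the coordinates, and 22076 of the gene identifiers were found in GENCODE mouse release 21, 17975 of them at the same chromosome, start and end.

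Expected counts were rounded to whole numbers. Total counts ran from 15.1 M to 68.8 M per library (median 34.8 M), so 3 counts, taken as the floor for an observed 0, correspond to 0.198 CPM in the shallowest female library. Floors cover counting error only. Genes were filtered with filterByExpr by sex, which left 16927. Sex was tested with edgeR 4.0.16 (R 4.3.3): TMM factors, quasi-likelihood fit and F test, no covariate, Benjamini-Hochberg adjustment, threshold 0.05, effect coded female minus male. Standard errors were taken as the absolute log2 fold change over the square root of F. All adjusted p-values for single genes are from this test unless another is named. The same tool tested the number bands beside sex, and the interaction of sex with band.

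Gene lists were fixed before the data were examined and tested with camera (limma 3.58.1) on log2 CPM with prior count 2 and a preset correlation of 0.01, adjusted over 28 lists. Fry and camera with an estimated correlation were run beside it. The spread between mice was tested by limma on absolute deviations from the sex median, for genes of mean CPM at least 1. Variability was ranked by edgeR's tagwise dispersion over its trend for genes of mean CPM at least 5, without a test. List scores, the mean log2 CPM of the members, were correlated in 20 pairs fixed beforehand, with two-sided permutation tests of 100000 resamples (Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1). With sex and band removed, scores were permuted within sex and band. Adjacent genes were compared with random pairs on different chromosomes in 1000 draws. GC content was taken from the longest GENCODE transcript of each gene, which existed for 99.6% of the tested genes.

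The text names, by a rule fixed beforehand, the 10 autosomal genes with the largest change in each direction (mean CPM at least 2, the same sign in all 4 bands, no placeholder symbols), 6 X-linked genes in each direction, up to 4 members of each list with the smallest adjusted p, preset single genes, the 15 most variable genes, and 5 genes for each further test and direction. Some genes that this rule picks are not reported here. Other names were chosen after their values were seen, and the text says so. Alternatives comprised DESeq2 1.42.0, limma-voom, other size factors and filters, covariates, each band alone, and the deposited values.

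On simulated counts for the same libraries, the sex test recovered 44% of 50 genes changed 1.1-fold, 86% at 1.25-fold, 96% at 1.5-fold and 100% at 2-fold, with 11 false calls among 16927 genes. The spread test recovered 97% of 200 genes made 1.5 times as wide among 5000, with 8 false calls, and camera called the 1 list shifted 1.15-fold. For these checks of spread and lists, genes were drawn independently and without band differences. They therefore do not show how camera with its preset correlation behaves on lists whose members vary together. Libraries were checked for duplicates: the closest pair correlated at 0.972 across genes, and the smallest chi-square per degree of freedom between a library and its nearest neighbour was 40.3, so every library was counted as its own sample. The animals' genotypes and the ERCC controls were not used here.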

Results

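Islet RNA was sequenced from female and male Diversity Outbred mice on the same diet. Number bands 1 to 4 held 46, 46, 49 and 47 females and 45, 48, 50 and 47 males (190 males in all). Total counts were alike in both sexes, with a median of 34.8 M counts in females and 34.9 M in males. Libraries of number band 4 were shallower, with medians of 23.97 M in females and 24.2 M in males, against 35.8 M to 37.8 M in bands 1 to 3. The series title names genetic drivers of islet function as its subject. The labels contain a single contrast, sex, and the mouse numbers allow a division into bands.

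The sex labels were checked first. Xist, the RNA of the inactive X chromosome, had a median of 1352 CPM in females and 0.744 CPM in males. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty had no count in any female library. Ddx3y, at 152.1 ± 45.8 CPM in males (SD, n = 190), was at least 766.7-fold higher in males when set against 3 counts in the shallowest female library, and the others were at least 423.6-fold (Eif2s3y), 186.6-fold (Kdm5d) and 247.7-fold (Uty) higher. No library went against its label on both Xist and the Y-linked genes (0 libraries). However, 2 females had little Xist, a band 2 female at 0.87 CPM and a band 4 female at 0.467 CPM, where the lowest of the other females had 332.5 CPM. The highest male had 16.7 CPM.

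**Figure D1:**
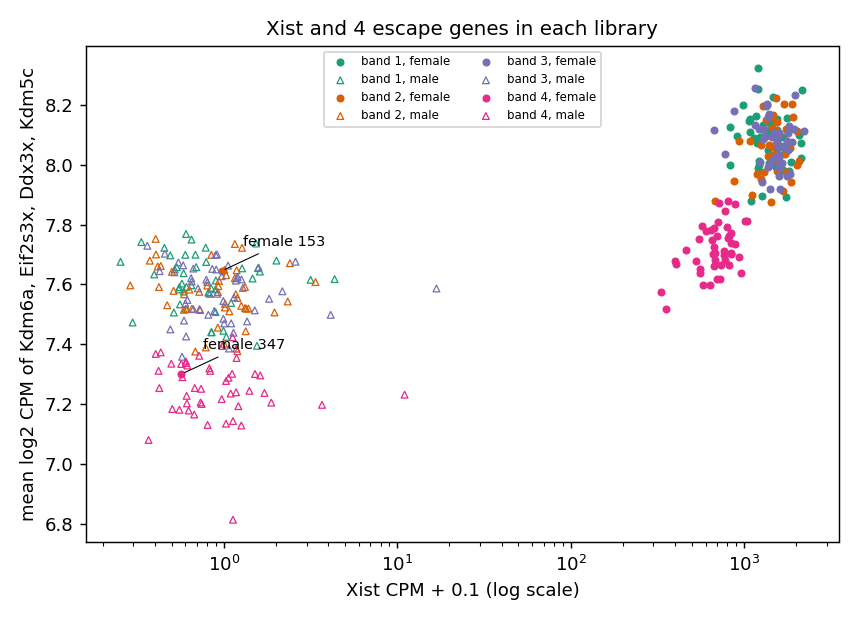
Xist CPM plus 0.1 on a log scale against the mean log2 CPM of Kdm6a, Eif2s3x, Ddx3x and Kdm5c, 4 genes that escape X inactivation, with a point for each library coloured by number band (filled circles female, open triangles male). The 2 females named by mouse number, at 0.87 and 0.467 CPM of Xist, lie among the males on both axes.

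The comparison of females with males asked how islet RNA differs by sex. The non-beta endocrine genes were higher in females. Gcg, which encodes glucagon (ENSMUSG00000000394, chromosome 2, 62474530 to 62483650, GRCm38), averaged 24336 ± 10305 CPM in females (SD, all females) and 11803 ± 6054 CPM in males (SD, n = 190), a 2.06-fold difference (log2 1.04 ± 0.07 SE, adjusted p = 7.88e-37). Of the 9 alpha cell genes 7 rose, among them the transcription factor genes Irx1 (0.91) and Irx2 (0.80) and the amino acid transporter gene Slc38a5 (1.03). Gc, the vitamin D binding protein gene, was the exception and fell by 0.76 on the log2 scale (SE 0.0814). In the delta and PP cell list 8 of 9 members rose, including Rbp4 (0.71), Pyy (0.66), Ptprz1 (0.59), the somatostatin gene Sst (0.56) and the pancreatic polypeptide gene Ppy (0.38). In single bands Sst missed the threshold in band 3 and Ppy in bands 1 and 3. Camera placed both lists above the other genes (adjusted p = 4.49e-08 for alpha and 1.6e-08 for delta and PP), and both held in each band alone and with an estimated correlation (adjusted p = 0.0075 each).

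The insulin genes moved the other way. Ins2 was 1.26-fold and Ins1 1.30-fold higher in males (log2 -0.33 ± 0.0365 and -0.38 ± 0.0509), and together they took 11.6 ± 2.52% of all counts in females and 14.3 ± 3.49% in males (SD). Ins1 and Ins2 had fractional counts in every library, so their division between both loci is uncertain. Iapp, encoding the co-secreted islet amyloid polypeptide, fell by 0.19, and so did Ero1lb, an oxidoreductase gene of the beta cell endoplasmic reticulum, by 0.19. Pdx1, a beta cell transcription factor gene, fell by 0.16, and the incretin receptor genes went apart, with Glp1r down (-0.15) and Gipr up (0.10). In the beta cell identity list 7 of 16 members fell and 0 rose. Its camera call (adjusted p = 0.0137) was lost with an estimated correlation (adjusted p = 0.229) and in band 4 alone (0.0593). The glucose transporter gene Slc2a2 did not pass (0.08, adjusted p = 0.262). Mafa, a beta cell transcription factor gene, did not pass in the pooled fit (0.08, adjusted p = 0.827) but was lower in females with the band as covariate (-0.29, adjusted p = 0.0159). With 6 scores for acinar, duct, endothelial, stellate, macrophage and lymphocyte genes as covariates, the insulin differences shrank to -0.17 for Ins1 and -0.18 for Ins2, and that of Gc to -0.47, while Gcg stayed at 0.87. These scores differed between bands too (19.8% of the variance for endothelial genes), and with the band added the values were -0.25, -0.21, -0.44 and 0.90 in the same order.

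Among autosomal genes of mean CPM 2 or more with the same sign in all 4 bands and no placeholder symbol, the largest difference was that of Aldh1a3, which encodes a retinaldehyde dehydrogenase used as a marker of dedifferentiated beta cells (ENSMUSG00000015134, chromosome 7, 66390890 to 66427517). It averaged 2.88 ± 2.78 CPM in females and 13.8 ± 28.1 CPM in males (SD), 4.76-fold higher in males (log2 -2.25 ± 0.179, adjusted p = 1.16e-27). Its log2 difference was -1.80, -2.14, -2.33 and -2.75 in bands 1 to 4. Also lower in females were Prss3 (-1.62), Dapl1 (-1.53), C1qtnf1 (-1.47), the lysine catabolism gene Aass (-1.39), Rps7 (-1.19), Derl3 (-1.17), Rasl10b (-0.98), Otoa (-0.97) and Snhg18 (-0.96). Higher in females were Tph1 (1.40), the serotonin synthesis gene, the vasopressin receptor gene Avpr1b (1.11), Slc28a2 (0.93), Igfbp4 (0.92), the GABA synthesis gene Gad2 (0.92), Otof (0.89) and Vip (0.84). Tph1 passed the test in bands 2 (2.67) and 3 (1.72) but not in bands 1 (0.40) and 4 (0.74). Prss3 did not pass in band 2 (-0.45, adjusted p = 0.536), Slc28a2 and Vip not in bands 1 and 4, and Gad2 not in bands 1 and 3, while the others passed in every band. Counts were whole in few libraries for Aldh1a3 (1.06%), Prss3 (3.7%), Rps7 (0%), Igfbp4 (8.47%) and Gad2 (20.6%), so reads shared with other loci make these values uncertain. Rps7 was at -2.54, -2.22, -2.41 and -0.47 in bands 1 to 4 (adjusted p = 0.00303 for the interaction with the band) and at -1.93 with the band as covariate, so its pooled value is not that of any band.

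**Figure D2:**
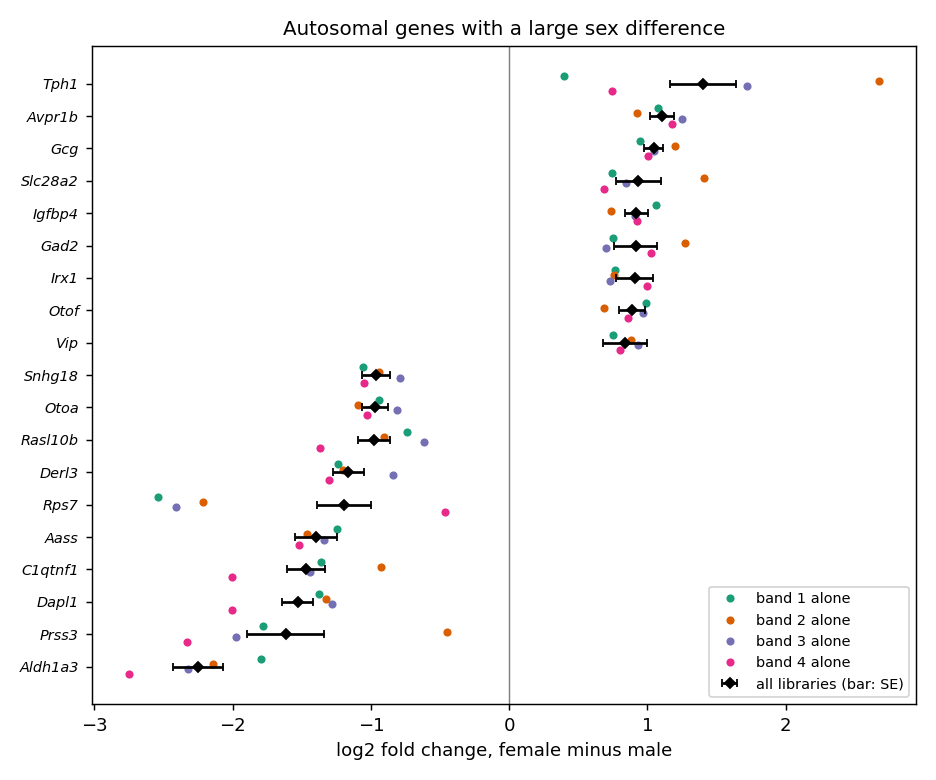
Log2 fold change, female minus male, for autosomal genes with a large sex difference. Diamonds give all libraries with the SE, and coloured points give each number band alone. All 4 bands share the sign for each gene by the rule that picked them, and Aldh1a3 runs from -1.80 to -2.75.

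Cell division and stress genes were lower in females. In the proliferation list 17 of 20 members fell, such as Ccnb1 (-0.93), Cdc20 (-0.84), Cdk1 (-0.82) and Rrm2 (-0.53), and 1 rose, Pcna (named after its value was seen). Levels were low, with Ccnb1 at 0.617 CPM in females and 1.18 CPM in males. In the unfolded protein response list 15 of 19 members fell and 0 rose, led by Trib3 (-0.73), Chac1 (-0.63), Herpud1 (-0.43) and Asns (-0.20). Of 13 endothelial genes 11 fell, including Tek (-0.35), Flt1 (-0.28), Tie1 (-0.26) and Pecam1 (-0.17). Of 10 hypoxia genes 6 fell, with Ankrd37 at -0.42, Pdk1 at -0.35, P4ha1 at -0.20 and Vegfa at -0.15. Camera called these lists with adjusted p = 0.000163 for proliferation, 4.49e-08 for the unfolded protein response, 0.000129 for endothelial cells and 0.0354 for hypoxia. With an estimated correlation none was called, at adjusted p = 0.354, 0.0885, 0.229 and 0.375 in that order, and hypoxia also missed the threshold with the band as covariate (adjusted p = 0.0522). Only the unfolded protein response was called in each band alone. Proliferation was not called in band 3 (adjusted p = 0.208), endothelial genes not in band 1 (0.142), and hypoxia not in bands 1 to 3 (0.184, 0.222 and 0.278), all with the direction downward.

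Of the genes that respond to prolactin and placental lactogen in islets 8 of 11 rose in females and 1 fell. Besides Tph1 these included Neb (0.73), the cytokine signalling inhibitor gene Socs2 (0.38), Ivd (0.31) and the prolactin receptor gene Prlr (0.15). The camera call (adjusted p = 0.00382) was lost with an estimated correlation (adjusted p = 0.0885). In single bands the list was upward but not called in bands 1 (0.165) and 2 (0.125), and called in bands 3 (0.00249) and 4 (0.00138), so its return in every band was not shown. In the steroid receptor list Pgr (0.81) and Gper1 (0.62) rose, at 0.682 and 0.517 CPM in females, Nr3c1 (-0.10) and Nr3c2 (-0.08) fell, and Esr1 (0.16, adjusted p = 0.144) did not pass.

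The other 20 lists were not called by camera. In the acinar list 0 of 18 genes rose and 1 fell, Bhlha15 (-0.08), and in the duct list 1 rose and 2 fell. The acinar list had a median log2 difference of -0.05 although camera put its direction upward (adjusted p = 0.555). In single bands camera called it upward in bands 2 (adjusted p = 0.0107) and 3 (0.0321), and it was downward without a call in bands 1 (0.251) and 4 (0.48). These tests used the preset correlation of 0.01, and that estimated over all libraries was 0.827 for this list. Of the stellate and fibroblast genes 2 rose and 5 fell, with the pericyte genes Rgs5 (-0.53) and Pdgfrb (-0.37) lower. The counts of rising and falling members were 1 and 1 for macrophage, 2 and 0 for lymphocyte, 0 and 0 for adipocyte, 1 and 2 for Schwann cell, and 0 and 4 for red blood cell genes. They were 2 and 3 for oxidative phosphorylation, 4 and 0 for mitochondrially encoded, 4 and 5 for fatty acid oxidation, 5 and 3 for cholesterol synthesis, and 4 and 4 for circadian clock genes. They were 3 and 6 for exocytosis and granule genes, where Stx1a rose (0.38) and Cpe (-0.22) and Scg2 (-0.32) fell, and 5 and 4 for disallowed and dedifferentiation genes. They were 0 and 2 for interferon response, 0 and 0 for MHC class I presentation, 0 and 1 for immediate early, 2 and 0 for NF-kB and isolation stress, and 2 and 2 for steroid receptor genes. Adjusted over the list alone, the 8 called lists gave the same counts except proliferation, with 2 rising, and hypoxia, with 7 falling. Among the other lists, the counts of rising and falling members adjusted over the list alone differed for acinar (0 and 0), stellate and fibroblast (2 and 6), lymphocyte (2 and 1), Schwann cell (2 and 2), oxidative phosphorylation (1 and 3) and interferon response (0 and 0). Median and mean log2 differences had unlike signs for lymphocyte (0.212 and -0.0301), Schwann cell (0.113 and -0.0276), steroid receptor (-0.0119 and 0.194), disallowed (0.118 and -0.19), fatty acid oxidation (0.00977 and -0.0267) and clock genes (0.0232 and -0.00627), and the duct list had a median of -0.0318 with camera upward.

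**Figure D3:**
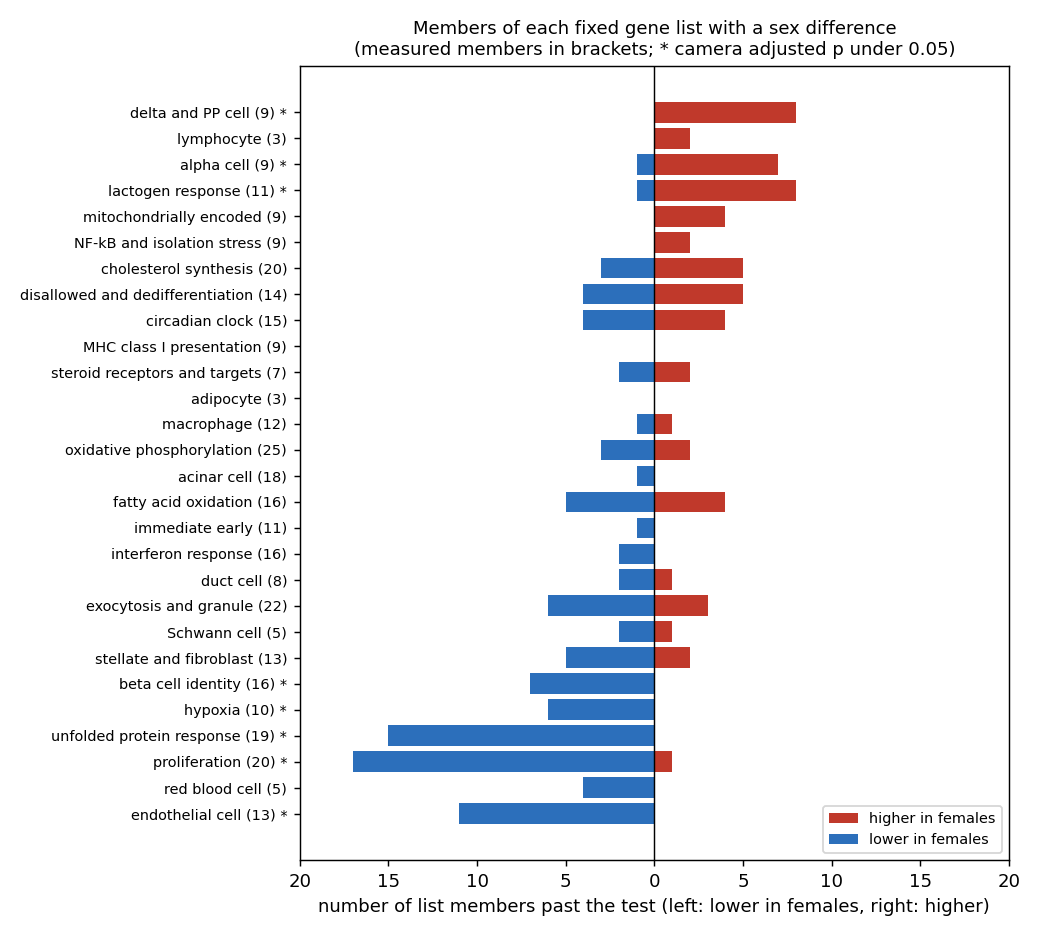
Number of members of each fixed gene list that were lower (blue, left) or higher (red, right) in females, with the measured members in brackets and a star where camera's adjusted p was under 0.05. In the delta and PP cell list 8 of 9 rose and in the unfolded protein response list 15 of 19 fell.

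In all, 7041 of 16927 genes differed by sex, 3119 higher and 3922 lower in females. Most differences were small: 1.96% of the tested genes were called at 1.5-fold or more (0.331% in the deposited values), and a test against a 1.2-fold minimum called 626. Which sex had more of these larger differences depended on the fit: 54.2% were higher in females here, 73.6% with limma-voom, 70.5% with 6 cell type scores as covariates, and 53.6%, 52%, 68% and 44.4% in bands 1 to 4 alone. Of the 7041 genes 5953 (84.5%) had the same sign in each of the 4 bands, and 785 were called in every band alone, 39.7% of them higher and 473 genes lower. The 7041 genes were picked in these same libraries, which favours a shared sign. The share of shared signs over all tested genes is not given here. Log2 fold changes of autosomal and mitochondrial genes correlated between bands at 0.598 to 0.709 across genes, which are not independent replicates. The band as covariate gave 8561 calls, 7032 of them shared with the pooled fit in the same direction.

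X-linked genes were more often higher in females than autosomal genes were, at 22.8% of 565 X-linked and 18.3% of 16340 autosomal genes, an odds ratio of 1.32 (95% interval 1.08 to 1.62, two-sided Fisher's exact p = 0.00796). The share lower in females did not differ detectably (24.4% and 23.1%, p = 0.478). For the share higher in females, the odds ratio in other fits ran from 1.228 (DESeq2, 95% interval 0.999 to 1.501, Fisher's p = 0.04765) to 1.475 (no filter, p = 2.57e-05). Xist and genes listed beforehand as escaping X inactivation were counted among the X-linked genes, and the share without them was not tested. Fisher's test treats genes as independent replicates, which they are not. Besides Slc38a5, X-linked genes higher in females were Kdm6a (0.75), Gria3 (0.61) and Klhl13 (0.54). Of 11 genes listed beforehand as escaping X inactivation 9 rose and 1 fell. X-linked genes lower in females were Serpina7 (-1.01), Xlr3b (-0.62), Tmem255a (-0.53), Dach2 (-0.53), Dcx (-0.50) and Asb11 (-0.47), of which Xlr3b and Tmem255a had mostly fractional counts. Xlr3b did not pass in bands 1 and 2 alone, Dach2 not in band 3, and Asb11 in band 4 only. Asb11 turned to 0.12 with limma-voom (adjusted p = 0.683).

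The spread between mice differed by sex for some genes, mostly with males wider. For Aldh1a3 the SD of log2 CPM was 1.92 in males and 1.07 in females (limma on absolute deviations, adjusted p = 3.88e-08). The cell division genes Cenpf (1.19 and 0.709), Tpx2 (1.12 and 0.682), Mki67 (1.04 and 0.619) and Cenpe (0.986 and 0.612) had SDs ordered alike, males first. The genes with wider spread in females were led by Pgk1-rs7, Dag1, Aldh9a1, Zfp609 and Chmp7, with SDs of 0.223 in females and 0.153 in males for Dag1. Of 14332 genes 423 differed in spread, 372 wider in males and 51 wider in females. Over all 14332 genes the difference was small in this fit, with 57.2% wider in males and median SDs of 0.36 in females and 0.366 in males. With band differences removed first, 743 genes differed in spread, with 729 wider in males. Over all genes 71% were then wider in males, with median SDs of 0.274 in females and 0.293 in males. In the deposited values 71.2% were wider in males, with median SDs of 0.215 and 0.23 in the same order.

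The number bands asked whether libraries differ in a way that sex does not describe. Band 4 stood apart. Cebpb was 4.98 log2 units and Mafa 4.73 higher in band 4 than in band 1, and H2afj (2.94), Vstm2l (3.45), Bri3 (2.28) and Mocs3 (2.13) were likewise higher, all among 14875 of 16927 genes that differed between bands. Bands 2 and 3 lay close to band 1, with median absolute log2 differences of 0.074 and 0.069 against 0.354 for band 4, and with 55 and 21 genes beyond 2-fold against 1560. The first principal component held 19.2% of the variance, of which 91.4% was between bands, and ran from 42.4 to 86.3 in band 4 and no higher than 16.5 in the others. Sex took 60.7% of the variance of the second. Across 16867 genes, which are not independent replicates, the difference of band 4 from band 1 correlated with the GC content of the transcripts at a Spearman rho of 0.746, against 0.12 for band 2 and 0.23 for band 3. In the deposited variance-stabilised values limma called 0 genes for band, with 0 at an unadjusted p under 0.05, and edgeR on the counts 14875. The smallest unadjusted limma p was 0.383 and the median F 0.0457. Random differences between mice alone would put some genes under 0.05, so band differences had evidently been removed from these values.

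**Figure D4:**
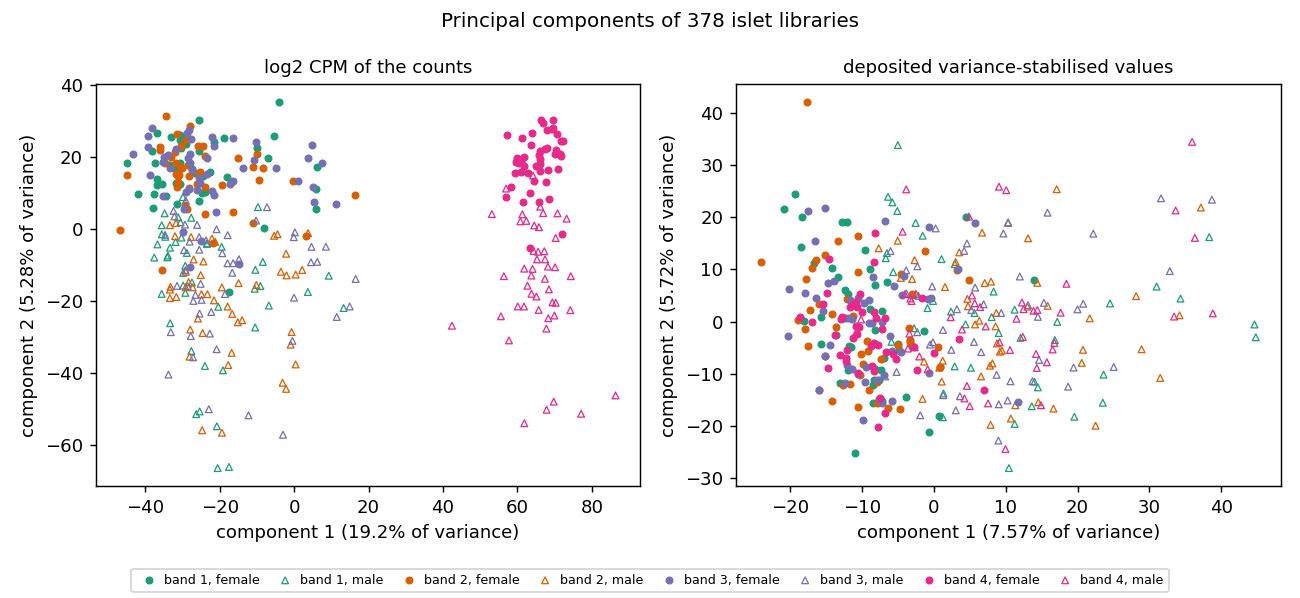
First and second principal components of all libraries, from log2 CPM (left) and from the deposited values (right), coloured by number band, with filled circles for females and open triangles for males. On the left band 4 lies at 42.4 or higher on the first component (19.2% of variance) and on the right the bands overlap.

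**Figure D5:**
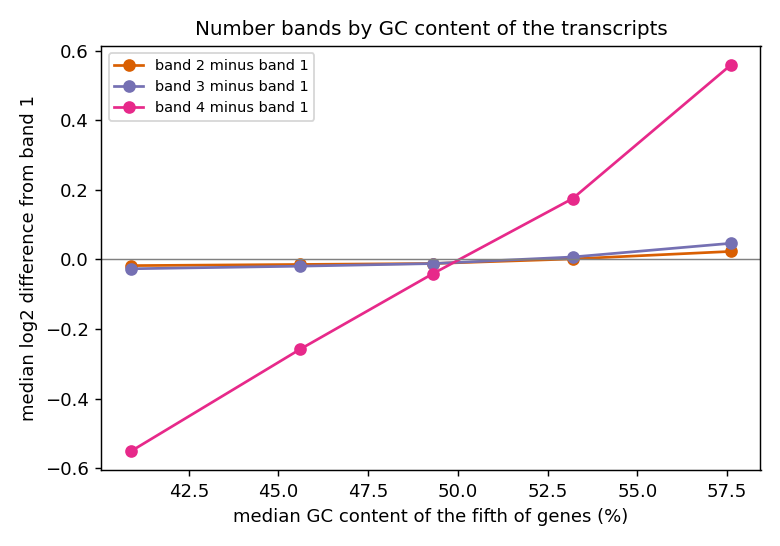
Median log2 difference from band 1 of genes divided by GC content into 5 groups of like size, against the median GC content of each group in percent, for bands 2, 3 and 4. Band 4 runs from -0.55 at 40.9% GC to 0.558 at 57.6% GC, and bands 2 and 3 stay near 0.

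Across mice, interferon response and MHC class I genes rose and fell together. With sex and band removed, their scores correlated at r = 0.905 (rho = 0.895, all libraries, permutation p = 1e-05, the smallest 100000 resamples can give, adjusted p = 2.22e-05), and at 0.868 to 0.93 within the 8 combinations of sex and band. Acinar with duct scores correlated at r = 0.71 (rho = 0.708), alpha with delta and PP scores at 0.578 (0.524) and proliferation with the unfolded protein response at 0.39 (0.371), at the same permutation p. Beta cell identity correlated with the disallowed and dedifferentiation score at -0.421 (rho = -0.401, same p). Without the 2 libraries farthest from the median of the first score of each pair, these were 0.904, 0.713, 0.57, 0.389 and -0.411. Pooled over sexes and bands, with the differences between these left in, they were 0.85, 0.70, 0.702, 0.451 and -0.181. Within the 8 combinations of sex and band the 4 pairs after interferon with MHC class I ran from 0.531 to 0.835, 0.21 to 0.695, 0.201 to 0.703 and -0.498 to -0.271. Of the 20 pairs 12 passed when pooled and 11 with sex and band removed. The pooled correlation of beta cell identity with endothelial genes is not given as a relation, because 56.4% of the variance of the beta cell score was between bands, and within bands and sexes it was -0.0415 (permutation p = 0.427).

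With sex and band removed, endothelial with stellate scores correlated at 0.388 (rho = 0.331) and macrophage with stellate scores at 0.325 (rho = 0.206, permutation p = 1e-05 for r and 6e-05 for rho). The macrophage pair was uneven, at 0.0277 to 0.576 within the 8 combinations of sex and band, and at 0.133 in females and 0.442 in males with the bands pooled. Immediate early with NF-kB and isolation stress genes gave 0.402 (rho = 0.381), and beta cell identity with oxidative phosphorylation 0.245 (rho = 0.306), each at permutation p = 1e-05. Within the 8 combinations the other 3 pairs ran from 0.249 to 0.549, 0.262 to 0.562 and 0.102 to 0.429 in the order given.

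The dispersion ranking was led by genes with fractional counts. Of its 15 genes, Hist2h2aa2, BC023719, Rps12, Rps12l1, Eno1b, Prss1, Pgk1-rs7, Amy2b, Rps3a2, Galnt2, Pcsk1n, Vcp-rs, Amy2a4 and Jund were not whole-numbered in 99% of libraries, which left Mafa. With sex and band in the design the log2 dispersion over the trend fell from 4.64 to 2.89 for Mafa, from 4.83 to 3.12 for Pcsk1n and from 4.58 to 2.50 for Jund. Amy2b had a 5th percentile of 1.93 CPM and a 95th percentile of 1830 CPM. Genes adjacent on a chromosome varied together: the median r of 16884 neighbouring pairs was 0.153, against -0.00797 to 0.00478 in 1000 draws of random pairs. It was 0.0809 with sex, band and 10 principal components removed.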

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

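For some genes the difference between females and males was not the same in every number band, by an interaction test planned before the data were examined. The run without the low-Xist females was chosen after the result was seen. The interaction of sex with band was called by edgeR for 1.09% of 16927 genes, and the log2 differences had unlike signs among the bands for 87.6% of these. The share over all tested genes is not given here, and genes with little sex difference take unlike signs readily. Some of these differences were small, as for Nploc4 (named after its values were seen) at -0.05, -0.07, -0.03 and 0.13 in bands 1 to 4. With bands reassigned at random within each sex, 1 of 22 assignments, the real one, gave as many genes, and the highest of the others gave 28 genes. The reassigned fits left the real band differences in the residual spread, which the real fit did not. Their counts are therefore not a like-for-like reference, and this comparison alone does not exclude chance. Within a band sex follows stretches of about 50 mouse numbers, so a difference between stretches of animals or in their processing would give the same result and is not excluded, and a change of the sex effect itself is not shown. Bglap3, an osteocalcin-related gene (adjusted p = 1e-09), was at -1.86, 3.48 and -1.76 in bands 1 to 3. The gastrin gene Gast (adjusted p = 4.73e-05) was at -0.19, -1.61 and -0.55. Neither had enough counts for a fit in band 4 alone. Amy1 (adjusted p = 0.000901) was at -1.08, 0.96, 0.68 and -0.13, and the immunoglobulin gene Ighm (adjusted p = 0.000901) at -0.12, 2.36, -2.08 and -0.19 in bands 1 to 4. Counts were whole in few libraries for Amy1 (1.59%) and Xist (1.32%) and in 55.3% for Bglap3, so reads shared with other loci make these values uncertain. In limma on the deposited values 0.998% of the tested genes were called, among them 67% of those called in the counts. EdgeR without the low-Xist females called 1.33%, among them 93% of those called with all libraries. In the deposited values these 4 genes were not called, at adjusted p = 0.359 (Bglap3), 0.499 (Gast), 0.125 (Amy1) and 0.941 (Ighm). Xist (adjusted p = 0.000273) was at 10.74, 10.68, 10.26 and 9.34 and passed in the deposited values too (adjusted p = 8.94e-07). Male medians were near the floor, at 0.832 CPM in band 2 and 0.724 CPM in band 4. The medians of the other females were 1499 and 703.7 CPM, so the smaller difference in band 4 came with lower female Xist in the band that stood apart. Single males at 16.7 CPM (band 3) and 10.9 CPM (band 4) also lower those differences. Without the 2 low-Xist females the adjusted p of Xist was 6.32e-06, so those libraries do not carry the call.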

How the results depend on the processing

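Chosen after the data were seen were the tests without band 4, with band and 6 scores, of lists with the band and an estimated correlation or in single bands, of interaction without the low-Xist females, of adjacent genes without overlap, and the whole-count ranking. The count of sex-differing genes stayed within 1.5 times of 7041 under all normalizations, filters, covariates and tools tried, but with 6 cell type scores as covariates only 4444 of the 7041 were shared in the same direction and 6 turned, and with the band added 4963 of 5861 calls were shared and 0 turned. The count fell with fewer libraries to 2873, 4687, 2632 and 4247 in bands 1 to 4 alone, and to 626 against a 1.2-fold minimum. Of the 28 lists camera called 8, and 2 with an estimated correlation, with or without the band (2), while fry, which asks another question, called 14. Genes differing in spread rose from 423 to 743 with the band removed and to 862 in the deposited values. Genes differing between bands went from 14875 to 0 in the deposited values, from which band differences are absent. Of the 15 most variable genes 4 remained by the variance of the deposited values. The causes of the other changes were not tested.

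For named genes 87.6% of 2755 values kept their side of the threshold and were not counted as turned, 10.1% no longer passed, 1.74% newly passed and 15 turned. Changes of sign with neither fit past the threshold are not among the 15. Mafa turned to -0.29 with the band as covariate and to -0.42 without band 4. Ighm turned to 0.66 (DESeq2), 0.60 (limma-voom), 0.24 (deposited values) and 2.36 (band 2 alone), and Asb11 to 0.12 (limma-voom). With 6 cell type scores Hba-a2 turned to 0.0544. In single bands, none past the threshold, S100b (0.0386) and Nr3c2 (0.00271) turned in band 1, Ndufb5 (0.0395) and Ndufa9 (0.023) in band 2, Hbb-bt (0.0462) in band 3, and Nr3c2 (0.0174) and Glp1r (0.0163) in band 4. Lists not called in the pooled fit were called upward in single bands by camera with the preset correlation of 0.01: NF-kB and isolation stress (adjusted p = 0.00471), MHC class I (0.00753), disallowed genes (0.0113) and interferon response (0.0445) in band 1, mitochondrially encoded (0.000173), acinar (0.0107) and oxidative phosphorylation genes (0.0479) in band 2, and acinar genes (0.0321) in band 3. Over all libraries the estimated correlations of these lists ran from 0.156 (disallowed) to 0.827 (acinar), so these p-values may be too small. Single bands were not tested with an estimated correlation. Beta cell identity with alpha scores turned to -0.143 with sex and band removed and to -0.332 in the deposited values, with delta and PP scores to -0.198 in the deposited values, and with endothelial scores to -0.0415 with sex and band removed. In the simulation 44% of 1.1-fold changes were recovered.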

Other observations

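Once genes with fractional counts were set aside, a ranking chosen after the first was seen and made with sex and band in the design, 11 of 25 genes were in the fixed acinar list, which has 13 members among the 6096 genes of mean CPM 5 or more with whole counts. Cpb1, a carboxypeptidase gene, ran from 20.1 CPM at the 5th percentile of mice to 1597 CPM at the 95th, and Pnlip, the pancreatic lipase gene, from 37.1 to 2741 CPM. Also ranked, and not in that list, were Reg1 (3.75 to 413.3 CPM), Kcnj5, a potassium channel gene (0.36 to 73.3 CPM), the neuropeptide Y gene Npy (0.695 to 105.7 CPM), Prkg2 (0.115 to 43.0 CPM) and the dopamine synthesis gene Th (24.7 to 505 CPM). These ranges are over all mice of different genotypes and were not tested.

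Among the tests below, those on library totals, on the band for alpha and delta genes, on Gc and the share of non-beta cells, and on the low-Xist females were chosen after the results were seen. Reassigning libraries to sexes at random gave at most 18 sex-differing genes against 7041, and at most 1 gene differing in spread against 423, and reassigning bands gave at most 78 genes against 14875. In each case 1 of 22 assignments, the real one, reached the observed count, the smallest share that 22 assignments can give. Single libraries grouped at random therefore did not give such counts. The fits with reassigned bands left the real band differences in the residual spread, so for the bands the counts are not a like-for-like reference. Libraries were reassigned singly, although sex follows stretches of mouse numbers. For the sex and spread counts, a difference between stretches of animals or in their processing is therefore not excluded by this comparison.

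The higher RNA of alpha, delta and PP cell genes in females was set against technical causes. If the insulin genes' hold on the library totals made it, the median log2 difference of the 18 members should fall near 0 once hormone and acinar genes are left out of the totals. It was 0.565, against 0.561 in the main fit. TMM factors were used in both fits, and the insulin share differed little between females and males (11.6% and 14.3% of counts). This run could hardly have moved the median, so it does not test that cause. With scores of 6 other cell types as covariates the median was 0.514, and the lowest value in any band alone was 0.46, so neither admixture of those cells nor the band accounts for the higher RNA. A larger share of non-beta cells in female islets may be the source, since 15 of the others rose, but a change of expression per cell predicts the same, and whole-islet RNA cannot tell these apart. It is not the whole cause for Gc, an alpha cell gene that went the other way (-0.76), and sex stays open as the biological explanation.

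The separation of band 4 is likely technical in large part. Its log2 difference from band 1 followed the GC content of the transcripts (Spearman 0.746 across 16867 genes, against 0.12 for band 2 and 0.23 for band 3), from -0.55 in the fifth of genes with the least GC (median 40.9%) to 0.558 in the fifth with the most (57.6%). The tables argue against lower depth as the cause, because the 30 libraries of bands 1 to 3 with totals no higher than the band 4 maximum of 31.1 M counts reached 4.67 on the first component, under the lowest band 4 library at 42.4, although only 2 of the 30 had totals no higher than the band 4 median of 24 M. Whether library preparation or sequencing caused the GC trend is not stated in the labels, and no biological difference between bands could be tested. The sex contrast had almost no GC trend (-0.0408).

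The 2 females with little Xist are unlikely to be mislabelled males, as their Y-linked CPM was 0. A candidate explanation is a single X chromosome, since their escape gene score lay 4.5 or more SDs under the other females of their band (z = -4.5 and -5.15) and within 1 SD of the males (0.82 and 0.48). Of the 4 genes in the score, Kdm6a was at 49.5 and 39.5 CPM, against own-band medians of 90.7 and 62.5 in females and 53.4 and 37.1 in males, but Kdm5c in the band 2 female (180.7 CPM) was near the females (183.4) and over the males (155.8). The score leaves out the rest of the 11 listed escape genes, which were mixed. By own-band medians, Pbdc1 and Ftx were nearer the other females in both libraries. Jpx, Mid1 and Utp14a were nearer the males or under both sexes. Having 2 active X chromosomes without Xist would raise X-linked genes as a class, and relative to the autosomes they differed from the other females by at most 0.0474 log2 units. Karyotypes were not used here.

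As a hypothesis, males with much Aldh1a3 RNA may have islets with more dividing cells. Across 190 males with the band removed, Aldh1a3 correlated with the proliferation score at r = 0.434 (rho = 0.383, permutation p = 1e-05 and 2e-05), at 0.289 to 0.612 in single bands and at 0.438 without the 2 farthest males, which fits the prediction. In females r was 0.152 (permutation p = 0.0355), and the difference between the sexes was not tested. The prediction that Aldh1a3 rises as beta cell identity genes fall was not settled: r = -0.208 (rho = -0.212, permutation p = 0.00418), between the bounds set for and against it, with -0.00241, -0.485, -0.157 and -0.196 in bands 1 to 4. The alpha cell score went the other way in males, at r = -0.328 (rho = -0.306, permutation p = 1e-05 and 3e-05) and -0.388, -0.261, -0.513 and -0.197 in bands 1 to 4, and r was 0.0401 in females (p = 0.59).

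The joint variation of neighbouring genes is not explained by gene models that overlap, since the median r of the 14135 adjacent pairs without overlap was 0.141.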
